A study of Mus musculus with 8 samples.

How the data were processed

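H3K27me3 libraries from 2 del/del and 2 del/fl samples were analysed, each with its own whole-cell extract library, which made 8 samples in all. The 4 whole-cell extract samples entered only as the control of each peak list. Per the labels' protocols, chromatin was crosslinked with formaldehyde and sonicated, puromycin was added 24 hours after transduction, and cells were harvested 7 days after transduction. Reads were handled with bcl2fastq and Bowtie 0.12.9 on mm10, per the submitters' processing notes. Peaks were called per sample with MACS2 2.1.0.20140616 in broad mode against the whole-cell extract, per the file headers, with a q-value threshold of 0.05, 1 tag kept per position and local background over 1000 and 10000 bp. The listed regions reached down to a q-value of 0.0983. The deposited pileup is a signal of stacked tags per region, per the file headers. The deposited fold enrichment is the ratio of that pileup to the local background, per the file headers. The p-value and q-value of each peak are deposited as −log10 by the authors' peak caller. These per-peak values are the authors' and were used to filter or rank peaks within a list, to recover the background, and to break ties. Control tags used numbered 20770551 and 31629404 in del/del and 19579060 and 15525700 in del/fl.

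From the lists, covered base pairs were counted per library with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. No chromosome lengths were used here, so a chromosome's span is its largest gene or peak coordinate (170.81 Mb for X). Gene names and coordinates came from a RefSeq table of the GRCm38.p6 assembly, the same build as mm10, with 34324 protein-coding and lncRNA genes. That table gives no strand, so the promoter window planned around the 5′ end was replaced by 2.5 kb to each side of both annotated ends. Peaks of all lists were merged where they overlapped by at least 1 bp or touched. A region or gene was gained when both del/del libraries and no del/fl library had a peak there, and lost in the opposite case. The percent of each gene-end window and of each 100-kb window covered by the deposited peaks was compared with limma 3.58.1 in R 4.3.3, with a variance trend, robust fitting and Benjamini-Hochberg adjustment. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated one. A group of 2 libraries cannot give an exact permutation p under 0.333. The labels do not say that the libraries came from separate embryos, so p-values measure only the spread between these samples. Per the growth protocol, established lines were divided into a transduced and an untransduced part, so libraries of the 2 genotypes can share a line. Which ones do is not stated, so tests were unpaired, and SDs and overlaps between genotypes can include differences between lines. No 2 lists shared identical intervals throughout.

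The interval code was tested on simulated lists, where it found 200 of 200 gained and 200 of 200 lost regions. limma was tested on simulated percents with 200 changed features. A first simulation drew noise from each feature's own SD and found 0 of the 200 in either kind of window. Those draws made variances more uneven than in the real 100-kb windows (prior degrees of freedom 1.79 against 59.9), so a second simulation, made after that result, drew variances from the fitted prior (6.54). It found 0, 8, 37 and 50 of 50 windows changed by 10, 20, 30 and 40 points, with 0 of 13785 unchanged windows called. At gene ends it found 0, 0, 5 and 23 of 50, with 50 of 8931 unchanged genes called, so gene calls are weak in both directions. With 353 X windows changed by 20 points it found 8. Both simulations stayed below the evenness of the real window variances.

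The design, the 16 gene lists, the named-gene rule and the alternatives were fixed before the data were examined. A further list, all X-linked genes, came from the annotation. The rule named, per direction, the 12 protein-coding genes gained or lost with the largest difference, gained or lost members of the Hox, imprinted, X inactivation and neural stem cell lists, up to 4 members of each other list, Smchd1, Xist and Firre, the 5 longest gained and lost regions on X and on autosomes, and the 5 windows with the smallest adjusted p per direction. Alternatives were a stricter peak threshold (−log10 q of at least 5), lists of equal length, leaving out each library, a replicate block, other windows, merging up to 3 kb, other scales and other filters. Settings for sharing variances, fits of autosomes only, base pairs gained or lost, and the other pairings of libraries under limma were added after the data were seen. Allele-specific signal, H3K27ac and Ctcf were not analysed here. A few genes and 1 window that the naming rule selects are not reported here.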

Results

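H3K27me3, the histone mark deposited by Polycomb repressive complex 2, was profiled by chromatin immunoprecipitation and sequencing in female mouse neural stem cell lines derived from E14.5 embryos. The lines carried 1 deleted and 1 conditional allele of Smchd1, which encodes a chromatin protein needed for silencing on the inactive X chromosome. Cells transduced with a Cre retrovirus lost the conditional allele (del/del) and were compared with untransduced cells (del/fl), with 2 libraries per genotype. The maternal X came from strain 129 and carried the deltaA allele of Xist, the RNA that starts X inactivation, and the paternal X was of Castaneus origin. MACS2 used 14064030 and 12819919 tags in the del/del libraries and 13288499 and 11793402 in the del/fl libraries, after duplicates were removed. The deposited lists held 32971 and 39982 peaks in del/del and 36934 and 45566 in del/fl, a difference within the spread between libraries. They were not separated by parental allele, so all values are for both X chromosomes together. Because only the del/del cells were transduced and selected, deletion and transduction were fully confounded in every comparison.

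The first comparison asked whether loss of Smchd1 altered H3K27me3 on the X chromosome. Peaks covered 51.0% ± 3.59 of X in del/del and 33.6% ± 2.94 in del/fl (SD, n = 2), a 1.52-fold difference. The fold ranged from 1.36 to 1.70 over the pairs of libraries. In length this was 82.7 and 91.4 Mb in del/del against 53.8 and 60.9 Mb in del/fl. On the autosomes the covered share was 1.57% ± 0.323 in del/del and 1.69% ± 0.338 in del/fl, and the libraries of the 2 genotypes overlapped. The mean was lower in del/del on 18 of the 19 autosomes (fold 0.849 to 1.01), which share their libraries and so are not independent. The covered share of X over that of the autosomes was 33.0 ± 4.52 in del/del and 20.1 ± 2.27 in del/fl. Both del/del libraries lay above both del/fl libraries, and an exact two-sided permutation test gave p = 0.333, the smallest value that 2 against 2 libraries allow.

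**Figure D1:**
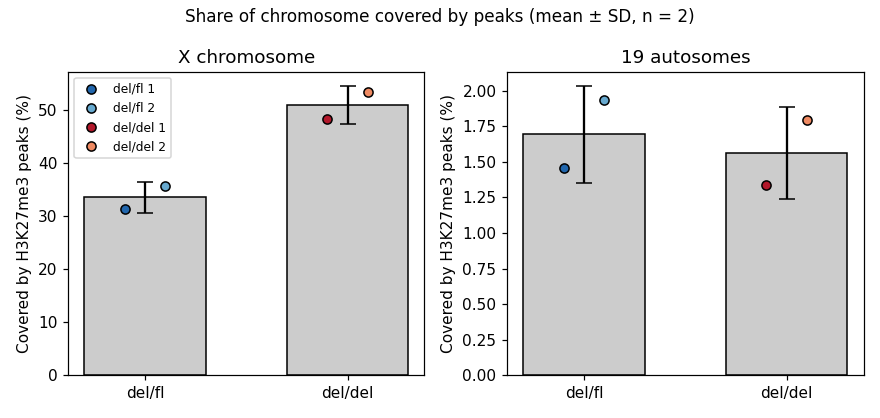
Share of X (left) and of the 19 autosomes (right) covered by H3K27me3 peaks, in percent, for each library (points) with the group mean (bars) and SD (error bars), n = 2; the vertical scales differ. Both del/del libraries lie above both del/fl libraries on X, while the genotypes overlap on the autosomes.

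At the deposited threshold the greater cover of X came with longer peaks and not with more of them. X held 15835 and 13581 peaks in del/del and 19355 and 18907 in del/fl, whereas with stricter peaks it held 452 and 217 in del/del and 127 and 97 in del/fl. The mean length of the X peaks at the deposited threshold was 5976 bp ± 1064 in del/del and 3000 bp ± 313 in del/fl. Peaks longer than 20 kb numbered 902 and 1144 in del/del against 187 and 330 in del/fl. Autosomal peaks had a mean length of 1800 bp ± 175 and 1910 bp ± 178, and peaks over 20 kb numbered 161 and 199 in del/del and 174 and 200 in del/fl. Counted as peaks per Mb in place of covered length, the X to autosome ratio was lower in del/del (fold 0.796), with overlapping libraries.

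Along X, stretches with some cover in del/fl, sparse or dense, were more covered in del/del, while nearly bare ones changed little. Of 171 windows of 1 Mb, 161 had a higher mean in del/del, and in 150 both del/del libraries exceeded both del/fl libraries. The largest difference, 40.5 percentage points, lay at X 63000001 to 64000000 (mm10), where cover was 47.5% and 63.7% in del/del and 14.0% and 16.2% in del/fl. The 43 windows with under 1% cover in both del/fl libraries differed by at most 2.70 points. 4933407K13Rik is the Dxz4 locus, at which the inactive X folds into a pair of large domains. Cover was 1.59-fold higher on its proximal side and 1.47-fold higher on its distal side. Proximal cover was 43.1% and 48.1% in del/del and 26.6% and 30.6% in del/fl. Distal cover was 52.7% and 57.8% against 35.4% and 39.7%, so the folds start from unlike levels and do not rank the sides.

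**Figure D2:**
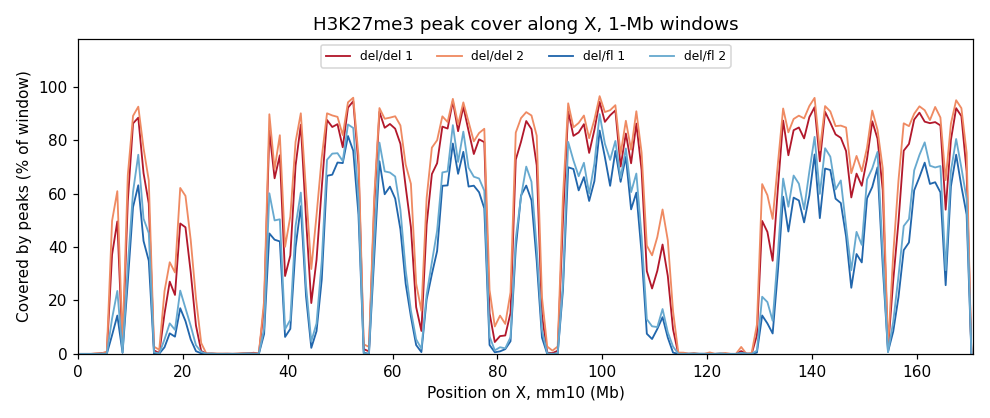
Percent of each 1-Mb window of X covered by H3K27me3 peaks (vertical axis) against position in mm10 (horizontal axis, Mb), 1 line per library. The del/del lines lie above the del/fl lines in the covered domains, and all 4 stay near 0 in the gaps between them.

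In windows of 100 kb, limma called 953 of 1476 X windows higher in del/del and 0 lower at an adjusted p of 0.05, and the median X window differed by 20.1 points. The smallest adjusted p on X belonged to the window at 158000001 to 158100000 over Cnksr2, with 82.4% and 89.8% cover in del/del and 28.4% and 37.8% in del/fl (limma, adjusted p = 3.06e-09). Windows at 62300001 to 62400000, which holds no annotated gene, at 83700001 to 83800000 in Dmd, the dystrophin gene, and at 20200001 to 20300000 over Slc9a7 differed by 51.2, 50.4 and 51.8 points. The other 2 ways to part the 4 libraries into pairs gave 0 called windows with the same variance setting. Those pairings mix the genotypes, so the X difference between genotypes enters their variance and holds X calls down in advance. Their 0 therefore does not measure false calls on X. The count of 953 rested on variances shared along the mean: without that trend limma called 2 X windows, and with each window's own variance 0. That last setting called 5 windows in all for genotype, and 22 and 5 for the other 2 pairings. The count was also not stable to leaving out a library: 298 X windows were called higher without del/del replicate 1, and 0 without any of the other 3 libraries.

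Gains and losses of whole regions were then counted. After all lists were merged into 59668 regions, 2550 had a peak in both del/del libraries and in neither del/fl library, and 1709 of these were on X. This was 13.1% of X regions and 1.81% of autosomal regions (odds ratio 8.18, 95% interval 7.51 to 8.91). In the opposite direction 1126 regions were lost, 16 of them on X (odds ratio 0.0502, Fisher's exact test p = 5.05e-96). Regions are not independent replicates, so these intervals and p-values describe the lists and not the genotypes. In base pairs, 13.7 Mb of X was gained and 0.153 Mb lost, against 17.7 to 26.9 Mb and 0.588 to 1.28 Mb when each library was left out in turn, and 2.07 and 0.0282 Mb with stricter peaks. The other pairings of the libraries gave between 0.485 and 2.11 Mb on X. Those pairings mix the genotypes, so a difference between genotypes also lowers their values. On autosomes 1.502 Mb was gained and 2.52 Mb lost, inside the 0.649 to 3.35 Mb of the other pairings.

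**Figure D3:**
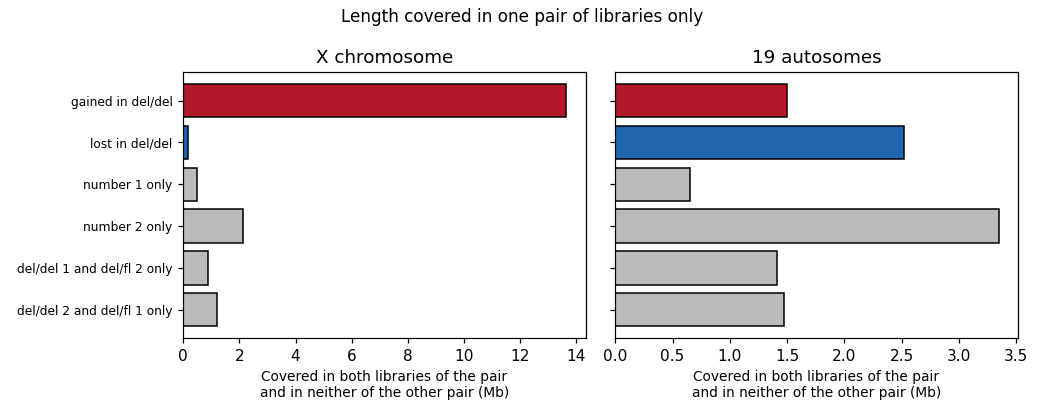
Length (Mb, horizontal axis) covered by peaks in both libraries of a pair and in neither library of the other pair, on X (left) and the autosomes (right), with different scales. Red and blue bars are the genotype pairs and grey bars the other pairings, which mix the genotypes. The 13.7 Mb gained on X exceeds every grey bar, and the autosomal gain and loss do not.

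The longest gained X region, at 20611192 to 20621080, spanned Ndufb11, a subunit of mitochondrial complex I, and Rbm10, an RNA-binding splicing regulator. Its peaks filled 65.4% and 79.3% of the region in del/del and 0% in del/fl. Others lay at 63316402 to 63325462, far from any gene, at 155555668 to 155563048 near Ptchd1, at 108894864 to 108902179 near Gm14870, and at 63844114 to 63851198. Among the lost X regions were 103625003 to 103626951, 1249 bp from Ftx, a noncoding gene of the X inactivation centre, and 18155461 to 18156784, 4078 bp from Kdm6a, a histone demethylase gene that escapes X inactivation. The others among the 5 longest overlapped Gm41891 and Vegfd or lay at 131950944 to 131952018. On autosomes the longest gained regions included 3 on chromosome 5 between 15491039 and 15591466, in and near Gm30613, Gm21149 and Gm21190. The window at 15500001 to 15600000 there was 47.8% and 55.9% covered in del/del and 2.09% and 4.14% in del/fl (limma, adjusted p = 3.06e-09). The longest lost autosomal region, 19922098 to 19926611 on chromosome 19, overlapped Gm32469. The other long gained regions lay on chromosome 10 at 66540478 to 66545658 and on chromosome 12 at 109107411 to 109112101, with Begain the nearest gene, and the other long lost ones on chromosomes 15, 5, 2 and 9, near Cyp2d34, Pitpnb, Gm34889 and 2310003N18Rik. limma called 31 autosomal windows higher and 12 lower. These counts were not stable: 10 and 1 were called when autosomes were fitted alone, 27 and 321 after division by each library's covered percent, 2486 and 70 without del/del replicate 1, and 0 in both directions without any of the other 3 libraries. The lower windows were led by 19700001 to 19800000 on chromosome 19, with 2.31% and 3.30% cover in del/del and 14.4% and 12.7% in del/fl (adjusted p = 0.000955). Other leading lower windows were at 10600001 on chromosome 18 over Esco1, Snrpd1 and Abhd3, and at 23300001 and 25800001 on chromosome 6, in Cadps2 and Pot1a.

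At genes, cover was measured within 2.5 kb of both annotated ends. A peak was present in both del/del libraries only at 157 genes, 31 of them X-linked, and in both del/fl libraries only at 202, 2 of them X-linked. The other pairings gave 39 to 473 genes, so these totals did not exceed the spread between libraries, and 0 to 2 X-linked genes, which the 31 gained did exceed. As these pairings mix the genotypes, a difference between genotypes also lowers their X-linked counts. Among gained X-linked genes, Ndufb11 was 66.2% and 86.7% covered in del/del, Plp2 19.3% and 45.7%, Klhl13, a ubiquitin ligase adaptor, 11.4% and 33.9%, and Zfp449 7.81% and 39.3%, all with 0% in del/fl. 4933403O08Rik, Gm46696 and Mageb17-ps were the other X-linked genes with large gains. Autosomal gains were largest at Gm21083 (57.0% and 48.2%), Speer4d (43.9% and 45.5%), Gm21190 (31.8% and 42.9%), Nmur2, a neuromedin U receptor (28.9% and 36.7%), and Gm21149 (19.5% and 28.7%). Losses were largest at Ttll9, with 18.2% and 26.2% cover in del/fl, Emb, the embigin gene, with 15.6% and 25.2%, Ifna1, an interferon gene, with 14.1% and 24.6%, and Smn1, the survival motor neuron gene, with 26.7% and 11.6%. Ptk6, Cnnm2, Ankrd45, Peli3, Olfr1359, Rph3al, Gm45618 and Aldoart2 followed, with means of 11.2% to 15.3% in del/fl. limma called 0 of 9131 genes at an adjusted p of 0.05, with 517 higher and 382 lower at an unadjusted p under 0.05. Of these, 143 of the higher and 379 of the lower genes were autosomal, together 6.47% of the 8064 autosomal genes tested. Among the 1067 X-linked genes the share was 35.3%, nearly all of them higher. The count of 0 did not hold in every setting: 64 genes, 54 of them X-linked, were called higher and 47 lower with stricter peaks, 1063 and 54 without del/del replicate 1, 263 and 1295 without del/fl replicate 1, and 296 and 1 without del/fl replicate 2. In simulated data the test found 0 of 50 genes changed by 20 points and 23 of 50 changed by 40.

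X-linked genes as a group were more covered in del/del. Mean cover at their ends was 66.9% and 70.4% in del/del and 49.6% and 55.5% in del/fl. Of 1067 with a peak in any library, 944 had a higher and 47 a lower mean, and 81 were higher and 0 lower when adjusted over the list alone. The set test camera gave an adjusted p of 2.45e-65 with a preset correlation and an adjusted p = 0.569 with an estimated correlation. Syn1, the synapsin I gene of neurons, was 32.6% and 51.8% covered in del/del and had a mean of 13.8% in del/fl. Pgk1 and Hprt, X-linked housekeeping genes, had means of 98.8% and 100% in del/del and 60.7% and 72.7% in del/fl, with one del/fl library far below the other. None of these 3 passed limma's test over all genes.

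Genes that escape X inactivation went the same way, with 5 of 7 tested members higher and 2 higher when adjusted over the list alone. Car5b was fully covered in del/del and 63.1% covered on average in del/fl, and Bgn, the biglycan gene, was 92.0% and 90.3% against 76.5% and 78.0%. Shroom4 and Utp14a varied more between libraries, with means of 66.3% and 46.2% in del/del and 37.2% and 31.8% in del/fl. The list had an adjusted p of 0.0459 (camera), and adjusted p = 0.967 with an estimated correlation. All its members are X-linked while most genes tested are autosomal, so this test cannot tell escape from X linkage. Over the 11 annotated members, 7 with a peak in any library, mean cover differed by 8.53 points. All X-linked genes differed by 16.1 points. Within the X inactivation region Ftx lost its peaks (12.5% and 8.32% in del/fl), and the list was not called (adjusted p = 0.777). Firre, a noncoding RNA gene of the inactive X, had 78.1% and 79.4% cover at its ends in del/del and 87.1% and 85.5% in del/fl (limma, adjusted p = 0.295). Over its whole span cover was 16.2% and 18.9% against 18.4% and 20.5%, with overlapping genotypes (exact permutation p = 0.667). Xist and Smchd1 held no peak in any library. Peak lists of this mark do not show whether Smchd1 was deleted.

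The 39 Hox genes, targets of Polycomb in most tissues, were fully covered in all 4 libraries. The Hoxa, Hoxc and Hoxd clusters were 100% covered throughout, and Hoxb was 95.05% ± 1.67 covered in del/del and 89.8% ± 1.82 in del/fl (exact permutation p = 0.333, n = 2). With 50 kb added on each side, the Hoxd region was 85.0% ± 4.26 in del/del and 91.3% ± 1.91 in del/fl. Developmental transcription factors had 81.0% and 82.0% mean cover, with 11 of 89 members higher and 26 lower (camera adjusted p = 0.728). Gata4 and Myod1 had means of 56.3% and 46.1% in del/del and 74.5% and 60.7% in del/fl, and Alx1 had means of 73.4% and 61.7%.

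Genes of Wnt, Bmp, Fgf and hedgehog ligands had lower cover in del/del at 27 of 35 tested members and higher at 8 (camera adjusted p = 0.0122). The call was lost with an estimated correlation, adjusted p = 0.967, and when autosomes alone were fitted, adjusted p = 0.0725. The set test compares the list with all genes, X-linked ones included. All autosomal genes tested had a median difference of -0.965 points, and the list had one of -2.40 points. The median of the list ran from -5.28 (without del/fl replicate 1) to 0.475 (without del/fl replicate 2) when each library was left out in turn. Fgf9 was 16.2% and 21.8% covered in del/del and 43.4% and 45.6% in del/fl, Fgf8 34.8% and 45.3% against 60.9% and 61.0%, and Fgf20 35.5% and 38.7% against 53.5% and 50.6%. Bmp4 had the opposite sign, with means of 86.4% and 73.0%. No member passed limma's test over all genes or over the list alone.

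Clustered protocadherin genes, which encode neuronal adhesion proteins, were sparsely covered, with 10 of 20 tested members higher and 10 lower (camera adjusted p = 0.939) and 1 lower when adjusted over the list alone. Pcdhb15 lost its peaks (8.95% and 9.42% in del/fl), as did Pcdhb16 (1.89% and 5.12%), and Pcdhac1 and Pcdha11 had means of 8.29% and 2.73% in del/del and 28.6% and 13.8% in del/fl. Of 17 imprinted genes with a peak, 7 were higher and 9 lower, and none was gained or lost (adjusted p = 0.939). Of 25 neural stem cell genes only 4 had a peak in any library, with 1 lower when adjusted over the list alone (camera adjusted p = 0.939). Sox1 was lost, with 1.83% and 2.28% cover in del/fl (limma over all genes, adjusted p = 0.295). Neuronal genes averaged 54.1% and 53.2% cover (adjusted p = 0.939), with means of 58.9% and 70.8% at Tbr1 and 39.99% and 24.3% at Th. At Rbfox3 the libraries had 21.6% and 28.4% in del/del and 36.9% and 35.1% in del/fl.

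Markers of other cell types did not separate the genotypes. Astrocyte and oligodendrocyte genes averaged 15.5% in del/del and 14.2% in del/fl, and endothelial and mural genes 27.9% and 28.1%. Microglial and blood genes averaged 3.65% and 5.30%, and fibroblast and mesenchymal genes 17.6% and 17.7%, with S100a4 gained at 8.36% and 8.08% and 1 member of that list higher when adjusted over the list alone. Each of these 4 lists had an adjusted p of 0.939 (camera), and pluripotency and germ line genes one of 0.999. Cell cycle inhibitors and housekeeping genes had 2 members each with a peak, too few for the set test. Among them Cdkn2a had means of 52.6% and 57.9% and Cdkn1c 42.8% and 49.4%, and Actb and B2m held no peak.

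Lists of the same genotype overlapped more on average than lists of different genotypes, mainly on X. The Jaccard index of covered base pairs averaged 0.631 within and 0.568 between genotypes. On X it was 0.704 and 0.608, and on autosomes 0.508 and 0.503. The ranges overlapped, since the pair of del/fl libraries reached 0.572 and the closest pair across genotypes 0.586. On X these were 0.617 and 0.651. On autosomes the highest index was across genotypes (del/del 1 with del/fl 1, 0.543), above both same-genotype pairs (0.502 and 0.514).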

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

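Peaks on the Y chromosome, which entered no comparison, numbered 23 and 63 in the del/del lists and 6 and 12 in the del/fl lists, although the lines are female. Of these, 20 and 60 in del/del and 4 and 10 in del/fl lay before the pseudogene Mid1-ps1. They covered 14565 and 31104 bp in del/del and 4001 and 8743 bp in del/fl, and no explanation was tested.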

How the results depend on the processing

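The higher X cover of del/del held under every setting run on covered length, with an X to autosome fold of 1.65 as reported, 1.61 with lists of equal length, 1.68 against the median autosome, 7.42 with stricter peaks and 1.49 to 1.81 leaving out each library. Only peaks per Mb turned it (0.796), because X peaks in del/del were fewer and longer at the deposited threshold. With stricter peaks X cover was only 3.51% and 2.34% in del/del and 0.431% and 0.420% in del/fl. The X to autosome ratio was then 5.11 in del/del and 0.689 in del/fl. The fold of 7.42 thus rests on a small part of the X cover. Variance settings, autosome-only fits and base pairs were added after the data were seen. Lines were divided before transduction, but the labels do not tie equal replicate numbers to one line. Deviations of same-numbered libraries correlated at 0.443 over windows (0.101 on X). In both genotypes replicate 2 had fewer tags used and more autosomal cover than replicate 1. The correlation thus cannot tell shared lines from depth or list size. The replicate block gave an X to autosome fold of 1.64, 1197 windows higher and 125 lower, 0 genes, and no changed list call. The block called 70 autosomal windows higher and 124 lower, and autosomal covered length had a fold of 0.920 between the libraries numbered 1 and 0.929 between those numbered 2. With stricter peaks the covered length differed by 3.17 Mb, the Jaccard difference was 0.118, 103 regions were gained and 72 lost, 87 genes gained and 75 lost, Hoxb differed by 10.5 points, and limma called 64 genes higher and 47 lower and 38 windows higher. Lists of equal length gave 656 lost regions, merging within 3 kb 1013 gained, and peaks over 0.5 of the region 1146 gained and 481 lost. Requiring overlap of 0.5 of a peak left a Jaccard-like difference of 0.0122. With 50 kb flanks Hoxa, Hoxb, Hoxc and Hoxd differed by -0.310, 7.12, 0.498 and -6.29 points. Limma called 14 genes higher and 7 lower within 1 kb. For windows it called 32 lower on the arcsine scale, 520 higher and 321 lower after division by each library's covered percent, 166 and 1 at 500 kb, and 10 and 1 on autosomes alone. Without robust fitting it called 10 genes higher and 1 lower, and 5 windows lower. Without the trend it called 2 windows higher and 0 lower, and with each feature's own variance 1 gene higher, and 3 windows higher and 2 lower. With an estimated correlation the adjusted p of X-linked genes was 0.569, and those of escape genes and of the Wnt, Bmp, Fgf and hedgehog list 0.967. The escape list also lost its call with stricter peaks (0.451), equal lists (0.123), 1 kb windows (0.479), gene spans (0.0605) and genes covered in 2 libraries (0.0916), and the ligand list with 1 kb windows (0.134), gene spans (0.0587) and autosomes only (0.0725). Leaving out each library gave 3388 to 17714 regions gained, 1622 to 13704 lost, 224 to 1023 genes gained, 327 to 1210 lost, 0 to 1063 genes called higher, 0 to 1295 lower, 0 to 2784 windows higher and 0 to 70 lower. The counts of gained and lost regions and genes rise there because fewer libraries have to match. Limma then has 1 library in an arm, assumed to vary like the others, and the cause of its wide ranges was not tested. Base pairs gained and lost on autosomes were 2.42 to 11.9 and 3.96 to 14.8 Mb leaving out each library, and 0.459 and 0.868 Mb with stricter peaks. They also gave a covered length difference of 16.6 to 36.6 Mb, a peak number difference of -9089.5 to -457.5, a Hoxb difference of 3.94 to 6.52 points, and an adjusted p of 0.0681 to 0.427 for escape genes and 0.00899 to 0.367 for the ligand list. The cause of the other changes was not tested. Regions near the q threshold in one library can fall below it in another.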

Other observations

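All tests in this part except the pair on the chromosome 5 segment were chosen after the result was seen. With 1-Mb windows of X grouped by their cover in del/fl replicate 1 and the change read against del/fl replicate 2 alone, the 48 windows under 1% differed by 1.31 points, those of 1% to 10% by 20.3 and those of 10% to 30% by 32.5. Those of 30% to 50%, 50% to 70% and 70% to 100% differed by 26.95, 17.3 and 10.1 points. Cover cannot pass 100%, which limits the change of windows with more cover, so this fall is not read as a trend.

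Of the 16 X regions lost in del/del, 2 lay at or next to a gene of the X inactivation or escape lists, against 184 of all 13077 X regions (Fisher's exact test, odds ratio 10.1, p = 0.0208). The test was run because Ftx and Kdm6a had been noticed among these regions, so its p overstates the evidence. Among gained X regions 17 of 1709 did so.

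The higher X cover of del/del may follow from the deletion, and technical explanations were weighed against that hypothesis. Greater ChIP read depth acting alone is argued against at the deposited threshold. There the deeper library minus the shallower one of the same genotype differed by -4.62 points of X cover on average (-5.07 in del/del and -4.16 in del/fl). Del/del replicate 2 covered 1.70 times as much of X as del/fl replicate 1 with 0.965 times the tags left after duplicates were removed. With stricter peaks the sign between depths turned. The deeper library then covered 3.51% of X against 2.34% in del/del, and 0.431% against 0.420% in del/fl. Before duplicates were removed both del/del libraries had more ChIP tags (24013734 and 21938857) than both del/fl libraries (20144605 and 18381858), and afterwards the genotypes overlapped. The deeper library was replicate 1 in both genotypes by either count. A fit of X cover to tags used and replicate number, without genotype, left residuals of at most 1.0996 points. With 4 libraries that fit had only 1 residual degree of freedom, so its closeness cannot decide whether depth and replicate explain X cover. The fit also used 30.6 points of X cover per step in replicate number. X alone thus leaves depth offset by a difference between replicates open. Autosomal cover does not settle that. With stricter peaks autosomal cover was lower in del/del in every pair of libraries (fold 0.927, highest pair 0.963). X cover was higher there in every pair (fold 6.87, lowest pair 5.42). At the deposited threshold the pair folds of autosomal cover went either way (0.692 to 1.23), as with lists of equal length (0.807 to 1.17). With stricter peaks the deeper library of each genotype had more X cover but less autosomal cover. Its autosomal cover was 13.99 against 14.22 Mb in del/del and 14.77 against 15.68 Mb in del/fl. Lower autosomal cover in del/del thus cannot exclude depth, and depth offset by a difference between replicates stays open. Fewer inactive X chromosomes in the del/fl cultures would lower the X background there relative to the autosomes. The X to autosome ratio of that background, taken at a high percentile over peaks, was compared between genotypes. Over pairs of libraries, the lowest value of del/fl over del/del was 0.996. That background was recovered only inside peaks, so a loss could pass unseen, and how large a loss was not tested. Transduction and puromycin selection cannot be told apart from the deletion, as 0 libraries were transduced without it. Control depth and ChIP duplicate rate also parted the genotypes, and neither was tested as a cause. Control tags used were 20770551 and 31629404 in del/del and 19579060 and 15525700 in del/fl. ChIP duplicate rates were 0.41 and 0.42 in del/del and 0.34 and 0.36 in del/fl.

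The peaks of del/del on chromosome 5 between 15400001 and 15700000 covered 29.3% and 31.6% of the segment, against 2.30% and 3.08% in del/fl. Reads shared across copies of the Speer family were tested on the 9 Speer genes outside it, whose median change was 0 points. Although this met the bound set beforehand for no sharing, only 2 of the 9 had a peak in any library, both only in del/del. Speer4c, at 15709505 to 15714298, lies just past the segment, so its change of 12.5 points can belong to the same stretch. Speer4a had 0% and 6.42% cover in del/del. The test thus cannot decide, and sharing among close copies stays open. More copies of the segment in the del/del lines would raise the local background, which was 1.05 times that of del/fl (0.910 to 1.22 over pairs of libraries), a range that crosses the bound set beforehand. Neither explanation can be told apart from a change of the mark, and the deletion stays an untested alternative.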
